A study of Homo sapiens with 2 samples.

How the data were processed

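RNA was measured in 2 libraries of the T3M4 line, 1 labelled control and 1 labelled C1GALT1 knockout, and the groups were taken from the sample titles and genotype labels. Per the labels' protocols, RNA was isolated with a column kit and was intact by its integrity numbers, and libraries were made with the Illumina TruSeq RNA kit. FastQC, TopHat2 2.0.9 and Cufflinks 2.2.1, with the builds hg19 and GRCh37, are named per the submitters' processing notes. The strand setting and the annotation are not given in the sources used here.

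Per the file headers, the authors deposited a Cuffdiff-style table of 60767 rows with FPKM for each library, a test status, a p-value and a q-value. Its q-value compares the reads of 2 libraries without replicates, as the authors deposited it. Per the file headers, further sheets hold the authors' calls, their 2-fold higher and lower lists, and Gene Ontology terms with an adjusted p-value and a number of genes as the authors deposited them. The 409 higher and 301 lower rows of those lists were recomputed from the FPKM and the q-value of 0.05 or less. A fold change column in the authors' deposited table held 2665 cells turned into spreadsheet errors and was not used, and 30 gene names had been turned into dates.

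The authors tested 13088 rows, 47657 rows have the status of not tested, and 22 rows the status of no estimate. The rows without an estimate are 21 mitochondrial rows listed at 0 in both libraries, and H19. They were left out of each count although the chosen design had not foreseen them, as were Y-linked rows, XIST and TSIX, in total 494 rows. FPKM summed to 1014364 in the control and 973302 in the knockout library, and 3 unnamed rows of 100 to 106 bp held 43.7% and 42.1% of these sums. Read counts and depth are unknown, since the ratios of low rows fell on no shared whole-read steps, so no counting interval is given.

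Log2 ratios were computed from FPKM plus a pseudocount of 1, knockout over control, over rows at 1 FPKM or more in at least one library. A gene counted as higher or lower at 2-fold or more on that scale. No p-value was computed, because each group had 1 library. The 32 gene lists and the rule for named genes were fixed before the data were examined. That rule took C1GALT1 and C1GALT1C1, the 15 largest and 15 smallest ratios among tested rows naming a single gene, up to 4 members of each list with the largest absolute ratio, and every member of the mucin, polypeptide GalNAc transferase and O-glycan core lists. Some genes that the rule takes are not reported here. Members counted only in rows of several genes were left out of the list values.

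Each list with at least 5 measured members was set against 10000 random lists of the same size, drawn within 20 bins of mean level, and described by the percentile of its median. This describes these libraries only. The method was tested on simulated data made from the 12490 rows of the comparison that name a single gene, with shuffled ratios, 400 draws per setting and 300 random lists each. Lists of 20 genes lay outside the central range in 4.25% of draws without a shift, in 73.8% with a log2 shift of 0.2 and in 99.8% with 0.4, and lists of 8 genes in 5.5%, 33.5% and 91.0%. The simulated lists were drawn at random like those they were compared with, so the rate without a shift was set by the design. Shuffling also removes shared changes of neighbouring or co-regulated genes. These rates therefore do not cover lists whose members vary together. Chromosome medians were compared with 10000 random sets of as many rows, and summarised in 10 Mb windows with at least 10 rows. With ratios shuffled over 13901 rows, the largest absolute chromosome median was 0.053.

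For the closing section, transcript length and GC content came from GENCODE v29 by gene name, for 10745 of 12490 rows (86.0%), and no coordinates of that build were used. A median regression on cubic terms of GC content, log length and log level was fitted without the genes under test and subtracted. In simulated data of 10745 rows, a set that followed a planted trend went from a median of 0.34 to -0.04, and a set shifted by 0.3 on such a trend went from 0.82 to 0.33. Ribosomal protein genes were matched to the 5 nearest other genes on length and level. Alternatives tried were another pseudocount, other minimum levels, fold sizes and scalings, unmatched random lists, a stricter q-value, and subtraction of the local median. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.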

Results

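RNA from T3M4, an established human cell line from a pancreatic ductal adenocarcinoma (PDAC), was sequenced in 2 libraries, with 1 library from control cells and 1 from cells in which C1GALT1 had been knocked out with CRISPR/Cas9. C1GALT1 encodes the core 1 galactosyltransferase, which adds galactose to the first sugar (GalNAc) of mucin-type O-glycans, so that its loss leaves O-glycans truncated. The values were the authors' FPKM (fragment counts scaled to transcript length and library size), and the depth of the libraries is unknown. With 1 library per group there were no replicates, so no difference below has a replicate check, and the authors' own test compares these 2 libraries, not the conditions. Ratios are given as log2 of knockout over control after adding a pseudocount of 1 to each FPKM, which understates the change of low genes, and coordinates are the locus regions of the authors' table on hg19.

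The knocked-out gene was considered first. C1GALT1 (XLOC_045131, chromosome 7, 7196564 to 7317410) stood at 16.8 FPKM in the control library and 13.99 FPKM in the knockout library, a log2 ratio of -0.25, so that the knockout library held 83.2% of the control level. C1GALT1C1, the chaperone that C1GALT1 needs to fold (XLOC_059945, chromosome X, 119759647 to 119764005), stood at 13.1 and 14.4 FPKM, a log2 ratio of 0.13. Most loci of chromosome 7 were higher in the knockout library, with a median log2 ratio of 0.34 over the other rows of the chromosome, and C1GALT1 lay 0.59 below that median (difference -0.59). Of the 72 other rows in its 10 Mb window, whose median was 0.25, 2 had a lower ratio than C1GALT1. A transcript carrying a small edit can still be counted, so the FPKM of the whole gene does not show whether the gene was disrupted.

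The comparison of the knockout with the control library asked which transcripts differ between PDAC cells with and without knockout of the core 1 enzyme. The highest ratios among rows of a single gene that the authors tested included PDPN (podoplanin, a mucin-type sialoglycoprotein of the cell surface), at 15.9 FPKM in the control and 98.2 FPKM in the knockout library, CDH11 (the mesenchymal cadherin-11) at 2.58 and 16.9 FPKM, and COL5A1 (a chain of type V collagen) at 1.52 and 10.2 FPKM. The lowest ratio among such rows belonged to NNMT (nicotinamide N-methyltransferase), at 94.3 and 1.42 FPKM, a log2 ratio of -5.30. DMBT1, a secreted scavenger receptor protein of mucosal epithelia, stood at 118 and 5.93 FPKM, and KRT13, a keratin of stratified epithelia, at 213 and 20.4 FPKM. CXCR4, the receptor of the chemokine CXCL12, stood at 6.203 and 0.56 FPKM.

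Across 13902 rows at 1 FPKM or more in at least one library, 285 were at least 2-fold higher in the knockout library and 270 at least 2-fold lower, and 88.9% differed by less than 1.5-fold. The median log2 ratio was -0.02, with an interquartile range of -0.18 to 0.18. Of these rows the authors had tested 13083, which held 205 of the higher and 172 of the lower rows. The counts depended on the pseudocount, and with one of 0.1 they were 514 and 444.

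**Figure D1:**
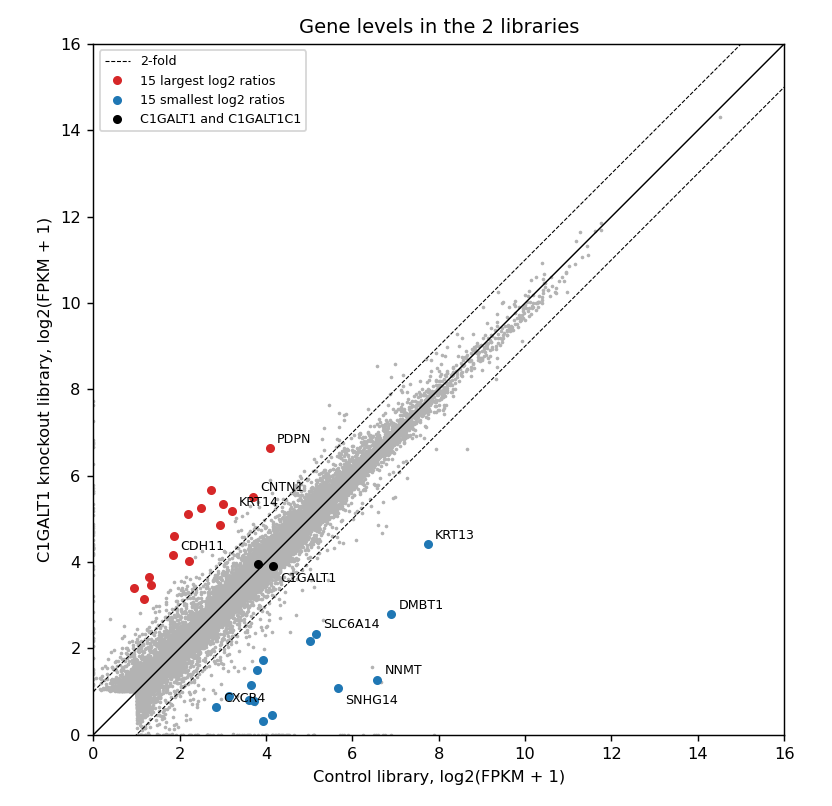
Level of each row in the control library (x axis) and the C1GALT1 knockout library (y axis), both as log2(FPKM + 1), with dashed lines at a 2-fold difference. Red and blue points are the 15 largest and 15 smallest log2 ratios among tested rows that name a single gene, and NNMT, at 94.3 and 1.42 FPKM, lies farthest below the diagonal among them.

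Other rows among the 15 largest ratios held genes of several kinds. KRT14, a keratin of basal epithelial cells, stood at 8.25 FPKM in the control and 35.1 FPKM in the knockout library. PI3, the elastase inhibitor elafin, stood at 6.60 and 28.0 FPKM, CNTN1, the adhesion protein contactin-1, at 12.0 and 44.6 FPKM, and PRSS21, the serine protease testisin, at 0.91 and 9.49 FPKM. RAB11FIP4, an effector of a recycling-endosome GTPase, stood at 2.66 and 23.3 FPKM, PLCH2, a phospholipase C, at 1.25 and 7.84 FPKM, and LRRC38, a regulatory subunit of potassium channels, at 6.99 and 39.4 FPKM. GAGE1, a cancer-testis antigen at 3.56 and 33.9 FPKM, belongs to a family of near-identical copies, so its value is uncertain. Also among them were the transcripts AL603831.1, RP11-669N7.2 and CTD-2535I10.1, at log2 ratios of 2.94, 2.74 and 2.35.

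The 15 smallest ratios also covered enzymes, transporters and adhesion genes. The citrullinating enzyme PADI2 stood at 11.2 FPKM in the control and 0.75 FPKM in the knockout library, the amino acid transporter SLC6A14 at 34.7 and 4.06 FPKM, and the stromelysin MMP10, a matrix metalloproteinase, at 11.7 and 1.23 FPKM. FERMT3 (kindlin-3, an activator of integrins) stood at 12.1 and 0.71 FPKM, RASIP1 (a Ras-interacting protein) at 14.3 and 0.25 FPKM, PDE3A (a cyclic nucleotide phosphodiesterase) at 16.5 and 0.38 FPKM, and the kinase PAK3 at 7.88 and 0.87 FPKM. SNHG14, a long RNA of the imprinted region of chromosome 15 (25068793 to 25492435), stood at 49.8 and 1.13 FPKM in a locus with 3 other expressed rows. TIGD1 and TSTD3, at log2 ratios of -2.86 and -2.21, also shared their loci with 3 other expressed rows each, so their values are uncertain where overlapping genes share reads. The same caution holds for MMP10, and for MMP1, GCNT3 and ALDH1A3 below, with 3 such rows each. It also holds for IFIT2 and IFIT3 (4 each) and TGFB1 (5). Some other named genes had fewer such rows, among them FERMT3 (2). A row named MIR663A was also among them, but it spans 26167555 to 26232162 of chromosome 20, far more than a microRNA, so no value is given for that microRNA.

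Genes of O-glycan synthesis, the pathway of the knocked-out enzyme, were mostly higher at its first step. Of 8 measured polypeptide GalNAc transferases, which attach the first GalNAc to proteins, 7 were higher in the knockout library, with a median log2 ratio of 0.47. GALNT1 stood at 15.8 FPKM in the control and 33.6 FPKM in the knockout library, GALNT2 at 27.1 and 42.4 FPKM, GALNT3 at 35.6 and 50.6 FPKM, and GALNT12 at 2.55 and 3.86 FPKM. GALNT6, GALNT9 and GALNT11 were also higher, at log2 ratios of 0.32, 0.60 and 0.33, and GALNT7 was lower, at -0.25. The median lay at percentile 99.9 of the medians of 10000 random lists of the same size matched on mean level, and 6 further members (GALNT5, GALNT13, GALNT14, GALNT15, GALNT16 and GALNT18) were below 1 FPKM in both libraries. GALNT4, GALNT8 and GALNT10 were counted only in rows shared with other genes, at log2 ratios of 0.02, -0.19 and -0.10, and with those rows the median was 0.33.

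Enzymes that build or sialylate the O-glycan cores went in both directions, with 5 of 11 higher and 6 lower, C1GALT1 and C1GALT1C1 included. The median of -0.25 (percentile 0.52) was the value of C1GALT1 itself, and without that gene the other 10 members had a median of -0.13, inside the range of random lists (percentile 9.47). GCNT3, a core 2 and core 4 branching enzyme, stood at 20.8 FPKM in the control and 8.86 FPKM in the knockout library, and ST3GAL4, a sialyltransferase, at 31.5 and 20.3 FPKM. ST3GAL1, which sialylates core 1, ST6GALNAC1, which makes the sialyl-Tn antigen, and the core 2 enzyme GCNT1 were lower at log2 ratios of -0.54, -0.52 and -0.32. The extending enzyme B3GNT3 stood at 25.2 and 33.2 FPKM, and ST3GAL2, ST6GALNAC4 and ST6GALNAC2 had log2 ratios of 0.26, 0.24 and 0.05. GCNT4, B3GNT6 and ST6GALNAC3 were below 1 FPKM in both libraries. Enzymes of N-glycan branching and capping had a median of 0.11 over 14 members and a mean of -0.03, inside the range of random lists (percentile 90.9), with B4GALT1, a galactosyltransferase, at 93.9 and 51.2 FPKM.

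Mucins, the heavily O-glycosylated proteins on which such glycans are carried, were mostly low in T3M4. Of 5 measured members 4 were lower in the knockout library, with a median log2 ratio of -0.53 (percentile 0.72). The SD of that median over resampled members was 0.61. MUC6, MUC2 and MUC5B lie near each other on chromosome 11 (1012571 to 1283406). They may not be independent, as the percentile takes members to be. The secreted mucins MUC2 and MUC6 stood at 1.88 and 1.77 FPKM in the control and at 0.19 and 0.014 FPKM in the knockout library, MUC16 at 2.13 and 1.17 FPKM, and MUC5B at 1.03 and 0.44 FPKM. MUC20 went the other way, at 18.2 and 42.9 FPKM, and was the only member at 5 FPKM or more, so that with that minimum the list's value became 1.20, while with no minimum the median was -0.14. MUC3A, MUC4, MUC5AC, MUC12, MUC13, MUC15, MUC17 and MUC21 stayed below 1 FPKM in both libraries, and MUC1 was counted only in a row shared with KRTCAP2 and RP11-201K10.3, at 194 and 183 FPKM.

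Genes of adhesion to the basement membrane were higher in the knockout library. Of 19 measured integrins and laminins (with the hemidesmosome collagen COL17A1) 14 were higher, 3 of them at 2-fold or more, and the median log2 ratio of 0.46 lay above all 10000 random lists. COL17A1 stood at 81.6 FPKM in the control and 186 FPKM in the knockout library, the laminin receptor subunit ITGA6 at 116 and 238 FPKM, and the laminin chain LAMA3 at 51.0 and 91.3 FPKM. Matrix proteases and their inhibitors had 10 of 16 members higher and a median of 0.23 (percentile 99.5) but a mean of -0.06. In that list the membrane protease ADAM8 (14.6 and 27.4 FPKM) was higher, while MMP10 and the collagenase MMP1 (33.7 and 9.66 FPKM) were lower.

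Epithelial markers were lower as a group, with 17 of 24 lower and a median log2 ratio of -0.16 (percentile 0.45). After subtraction of the local median it was -0.10, inside the range of random lists of unsubtracted ratios (-0.124 to 0.098). At 5 FPKM or more it was -0.124, at the edge of that range. No random lists were drawn for these settings, so whether the list would still lie outside is unknown. KRT7, a keratin of ductal epithelium, stood at 400 FPKM in the control and 97.2 FPKM in the knockout library, and the tight junction protein CLDN1 at 103 and 41.0 FPKM, while CLDN4, another claudin, stood at 32.9 and 67.6 FPKM. Mesenchymal markers were split, with 9 of 16 higher and 7 lower and a median of 0.29 (percentile 99.8), which was 0.04 over all 25 members with no minimum level and 0.67 over the 6 at 5 FPKM or more. COL5A1 and the transcription factor TWIST2 (1.07 and 3.28 FPKM) were higher, and the transcription factor SNAI1 (3.68 and 0.99 FPKM) and the actin-binding protein TAGLN (2.66 and 0.52 FPKM) were lower. Genes of the basal-like PDAC subtype had a median of -0.05 over 20 members (percentile 37.3), and of the classical subtype only 4 of 24 listed genes could be compared, with a median of -0.16 and ANXA10 as the most abundant at 28.1 and 35.9 FPKM.

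Interferon-stimulated genes were lower in the knockout library, 20 of 25 members, with a median log2 ratio of -0.40 that lay below all 10000 random lists. The antiviral genes RSAD2 (6.72 FPKM in the control and 0.77 FPKM in the knockout library), IFIT3 (20.4 and 7.43 FPKM), OASL (46.9 and 18.9 FPKM) and IFIT2 (11.3 and 4.72 FPKM) had the smallest ratios. Immediate early genes were lower too, 11 of 17, with a median of -0.20 (percentile 0.95). After subtraction of the local median it was -0.159, inside the lower bound of -0.166 from random lists of unsubtracted ratios. No random lists of subtracted ratios were drawn, so whether the list would still lie outside is unknown. Lower members included the phosphatase DUSP1 at 6.04 and 2.17 FPKM, the nuclear receptor NR4A1 at 14.02 and 7.84 FPKM and FOS at 3.81 and 2.09 FPKM. IER5, an early gene of the same list, stood at 22.8 and 34.9 FPKM. Inflammatory cytokines and chemokines had a median of -0.16 and a mean of 0.13 over 13 members (percentile 4.91, inside the range of random lists), and the median turned to 0.24 over the 7 members at 5 FPKM or more. The interleukins IL1A (11.4 and 38.6 FPKM) and IL1B (4.71 and 18.2 FPKM) and the NF-kappaB inhibitor TNFAIP3 (1.02 and 3.48 FPKM) were higher, and IL6 (4.39 and 0.73 FPKM) was lower.

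Among metabolic and secretory lists, genes of the unfolded protein response were higher by a small amount, 19 of 26, with a median log2 ratio of 0.17 (percentile 99.9). PDIA4, a disulfide isomerase of the endoplasmic reticulum, stood at 112 FPKM in the control and 199 FPKM in the knockout library, and the stress transcription factor ATF4 was lower, at 276 and 199 FPKM. Of the cholesterol synthesis genes 18 of 21 were higher, with a median of 0.13 (percentile 98.5), led by MSMO1 at 24.3 and 38.3 FPKM. S100 and annexin genes, which encode calcium-binding proteins, had 12 of 16 members higher and a median of 0.16 (percentile 99.5), with S100A9 lower, at 15.03 and 4.67 FPKM. In all, 12 of the 26 lists with at least 5 measured members lay outside the central 95% of random lists. Of these, 7 were higher and 5 lower. Chance alone would give 1.3 lists outside if members varied independently, which neighbours such as MUC2, MUC5B and MUC6 may not. Without C1GALT1 in the O-glycan core list, 11 lists lay outside, 4 of them lower. These counts are for ratios without subtraction of the local median.

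**Figure D2:**
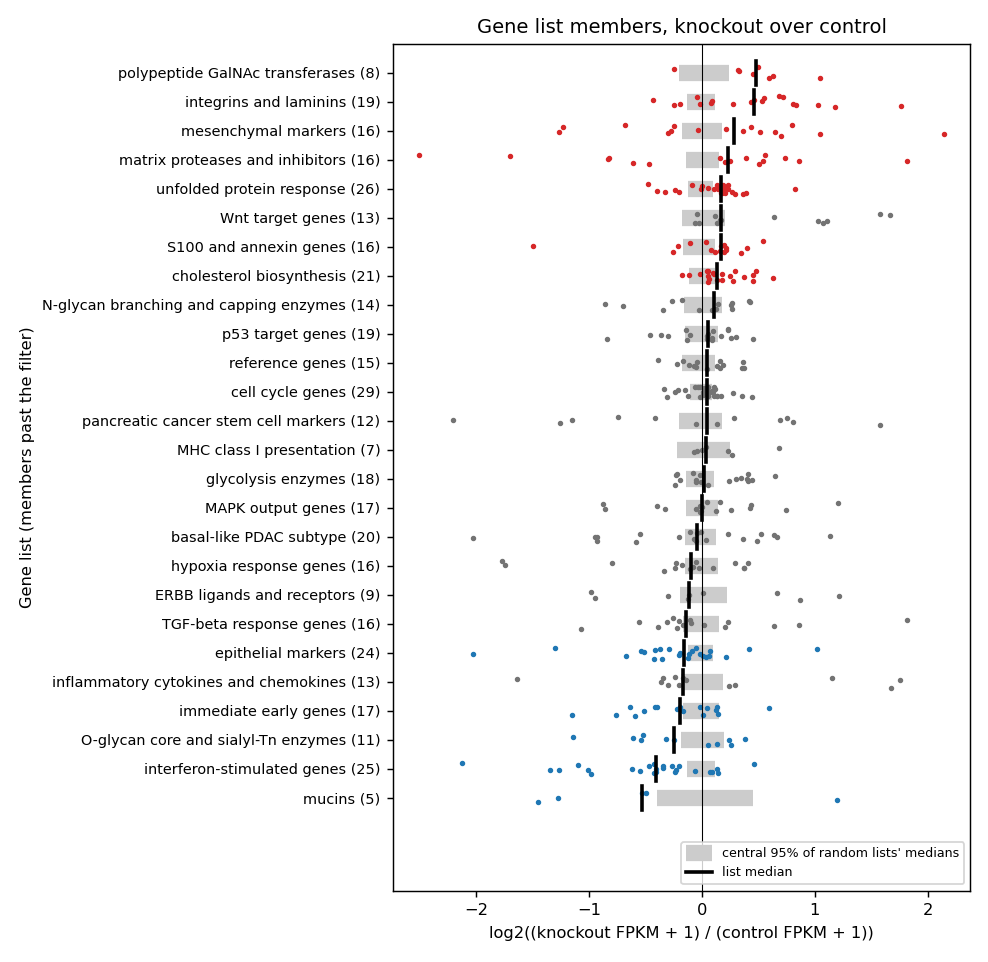
Each point is the log2 ratio of a list member in knockout over control (x axis), each row is a gene list with its number of measured members, black bars are list medians and grey bars the central 95% of the medians of random lists. Lists whose median lay outside the grey bar are red (7 lists, higher) or blue (5 lists, lower, of which the O-glycan core list lay inside without C1GALT1), from -0.53 for mucins to 0.47 for polypeptide GalNAc transferases.

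The other 14 lists lay inside that range. Of 13 Wnt target genes 10 were higher, 5 of them at least 2-fold, and none was 2-fold lower, with a median of 0.17 and a mean of 0.58 (percentile 95.7), and a median of 1.08 over the 7 members at 5 FPKM or more. The 2-fold higher ones included the Wnt antagonist SFRP1 (12.9 FPKM in the control and 43.2 FPKM in the knockout library), the hyaluronan receptor CD44 (56.5 and 171 FPKM), the ligand WNT7A (3.595 and 8.89 FPKM) and the pathway inhibitor NKD2 (6.15 and 14.1 FPKM). Several other lists held members far apart in both directions. Stem cell markers of pancreatic cancer had 6 members higher and 6 lower (median 0.04, mean -0.13, but a median of -0.41 over the 9 members at 5 FPKM or more), with CD44 higher and CXCR4, the kinase DCLK1 (7.58 and 2.59 FPKM) and the aldehyde dehydrogenase ALDH1A3 (18.7 and 7.88 FPKM) lower. Among ERBB ligands and receptors (median -0.12, mean 0.03), the ligands NRG1 (26.4 and 62.6 FPKM) and TGFA (13.8 and 26.0 FPKM) were higher and EREG (29.3 and 14.4 FPKM) and AREG (6.64 and 2.97 FPKM) lower. Among MAPK output genes (median 0.0022, or 0.11 after subtraction of the local median), the AP-1 subunit FOSL1 stood at 37.4 and 87.4 FPKM and the feedback inhibitor SPRY1 at 13.5 and 6.88 FPKM.

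Hypoxia response genes had a median of -0.09, with the glucose transporter SLC2A3 at 16.7 FPKM in the control and 4.19 FPKM in the knockout library and the carbonic anhydrase CA9 at 4.27 and 0.57 FPKM. TGF-beta response genes had a median of -0.14 and a mean of 0.02, with the ligands TGFB2 at 11.1 and 4.75 FPKM and TGFB1 at 21.9 and 40.6 FPKM. Cell cycle genes (median 0.04 over 29 members), glycolysis enzymes (0.02 over 18), p53 targets (0.05 over 19, mean -0.02), MHC class I genes (0.04 over 7) and reference genes (0.04 over 15) also lay inside the range. No member of those 5 lists differed by 2-fold, and the reference genes ran from RPLP0 at -0.39 to the cyclophilin PPIA at 0.37.

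Most markers of other cell types counted in rows of a single gene were below 1 FPKM in both libraries. None of the 8 MHC class II or 11 acinar and islet genes in such rows reached 1 FPKM, the highest being 0.18 and 0.067 FPKM. HLA-DMA and HLA-DMB, class II genes counted in a shared row, stood at 1.22 and 2.18 FPKM. Of the leukocyte markers in single-gene rows only CD14 passed, at 0.99 and 1.06 FPKM, and of the endothelial markers in such rows only ENG, at 10.98 and 11.4 FPKM. The fibroblast markers that passed in such rows were the collagen COL1A1 (4.86 and 4.72 FPKM), the actin ACTA2 (1.997 and 3.27 FPKM) and the proteoglycan LUM (2.203 and 0.22 FPKM).

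Loci of chromosome 7 were higher and loci of chromosome 15 lower in the knockout library as whole chromosomes. The median log2 ratio over 674 rows of chromosome 7 was 0.34, with 86.2% of rows higher, and that over 446 rows of chromosome 15 was -0.26, with 85.9% lower. The values given above for single genes were not adjusted for these shifts. Such genes include CLDN4, PDIA4 and PPIA on chromosome 7 and GCNT3 and ALDH1A3 on chromosome 15. The central 95% of medians of random sets of as many rows lay between -0.04 and 0.0071 for chromosome 7 and between -0.05 and 0.01 for chromosome 15. Chromosome 16 had a median of 0.16, with windows from 0 to 40 Mb at 0.26 to 0.36 and those from 50 to 90 Mb at -0.06 to -0.02, and chromosome 5 had a median of -0.14.

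**Figure D3:**
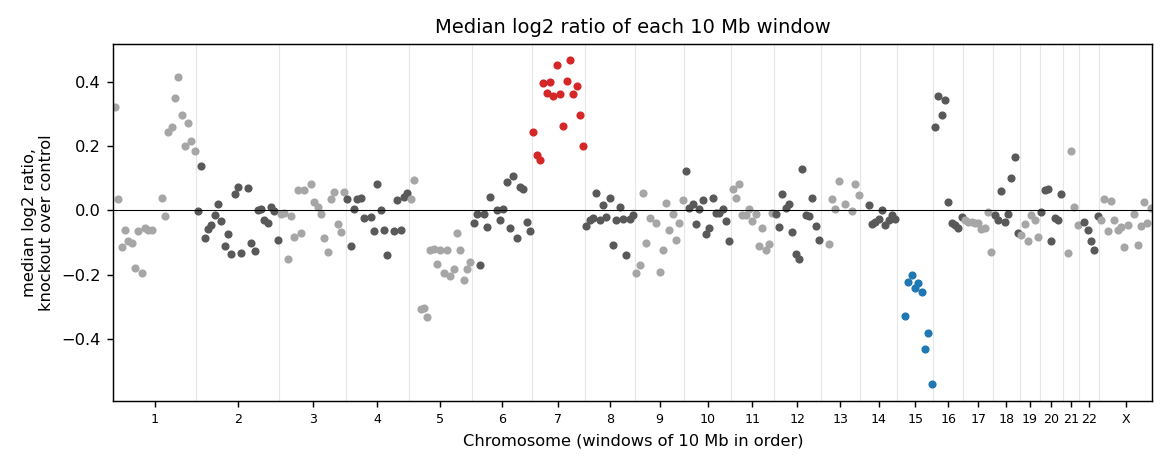
Median log2 ratio of knockout over control (y axis) in each 10 Mb window with at least 10 rows, in order along chromosomes 1 to 22 and X (x axis). All 16 windows of chromosome 7 (red) lie above 0 and all 9 windows of chromosome 15 (blue) lie below 0, as do all windows of chromosomes 17, 19 and 22, whose medians were nearer 0 (-0.04, -0.05 and -0.07).

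In the authors' deposited table, 6971 of 13088 tested rows (53.3%) had a q-value of 0.05 or less, 3405 of them higher and 3566 lower in the knockout library, and 5220 of these calls were under 1.5-fold. C1GALT1 had a q-value of 0.0027 and C1GALT1C1 of 0.0188 in the authors' deposited table. The authors' 2-fold lists take FPKM ratios without a pseudocount and a q-value of 0.05 or less. Their 409 and 301 rows are therefore not on the scale of the 205 higher and 172 lower tested rows given above. The authors' deposited table of Gene Ontology terms for the 409 rows at least 2-fold higher gave anatomical structure development (81 genes, adjusted p 0.0012) and positive regulation of vascular endothelial growth factor production (adjusted p 0.00853), which rested on 6 genes that included IL1A and IL1B. For the 301 rows at least 2-fold lower, the authors' deposited table gave developmental process (80 genes, adjusted p 3.3e-05), protein citrullination (4 genes, adjusted p 0.000646) and type I interferon signaling (8 genes, adjusted p 0.00726). Those 8 genes were RSAD2, IFITM1, OASL, IFIT3, IFIT2, IFIT1, ISG20 and IFI27.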

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

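The settings restricted to tested rows, with local medians subtracted, with rows of several genes included, or without C1GALT1 in its list were chosen after the data were examined. Against 285 rows higher and 270 lower at 2-fold, a pseudocount of 0.1 gave 514 higher and 444 lower, a 1.5-fold limit 884 and 654, and a 3-fold limit 97 and 135. A minimum of 5 FPKM gave 194 higher and 173 lower, and tested rows alone 205 higher and 172 lower. Dropping the minimum changed neither count because the pseudocount keeps lower rows from reaching 2-fold, so that setting tests nothing. With fewer members at 5 FPKM, the mucin median reversed to 1.20 (MUC20 alone), the mesenchymal median became 0.67 (6 members), the inflammatory 0.24 (7), the Wnt target 1.08 (7) and the stem cell marker -0.41 (9). With no minimum, which adds genes near 0, the mesenchymal median was 0.036 (25), the mucin -0.14 (13) and the O-glycan core -0.011 (14). The O-glycan core median was -0.098 at 5 FPKM, -0.13 with the local median subtracted, and -0.13 (percentile 9.47) without C1GALT1, whose value it had been. With a pseudocount of 0.1 the mucin median was -1.07. Epithelial markers were at -0.10 both with equal sums and with the local median subtracted. Immediate early genes were at -0.159 with the local median subtracted. The polypeptide GalNAc transferase median became 0.33 both with no minimum (14 members) and with rows of several genes (11). Scaling both libraries to equal sums raised ratios by a median of 0.06. This took the unfolded protein response to 0.24, cholesterol synthesis to 0.20, S100 and annexin genes to 0.23 and cell cycle genes to 0.10. The 3 highest rows, of 100 to 106 bp, held 43.7% of the control and 42.1% of the knockout sum, so that scaling depends strongly on them. With the local median subtracted, interferon-stimulated genes were at -0.32, cell cycle genes at 0.068 and MAPK output genes at 0.11; the cause was not tested. At 5 FPKM, chromosomes 4, 5, 7, 9 and 10 had medians of -0.019, -0.16, 0.38, -0.074 and 0.0096. The C1GALT1 ratio stayed between -0.26 and -0.19 over its alternatives, though the scalings could shift it by no more than 0.066. All 26 list percentiles kept their side of the central range against unmatched lists. Under other pseudocounts and scalings 385 values of named genes moved by less than 0.18, the spread over all rows, and 47 by more. Centring on the median and equal sums moved named genes by at most 0.018 and 0.066, so neither could pass 0.18. All 47 larger moves therefore came from the pseudocount of 0.1, under which 144 rows were compared. The authors' calls stayed within 1.5 times of their number with a stricter q-value. A minimum of 1 FPKM left them unchanged, but 13083 of the 13088 tested rows reach it, so that setting tests little. No paired analysis was possible because each group had 1 library. Unknown depth limits the rows of low FPKM most.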

Other observations

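The tests of chromosome windows, of imprinted genes and of ribosomal protein genes matched on protein-coding transcripts were chosen after the results were seen, as were the genes named in the next paragraph.

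All 4 peptidylarginine deiminases that passed the minimum were lower in the knockout library. These enzymes convert arginine to citrulline in proteins. PADI2 stood at 11.2 FPKM in the control and 0.75 FPKM in the knockout library, PADI1 at 2.11 and 0.32 FPKM, PADI4 at 1.95 and 0.35 FPKM, and PADI3 at 1.28 and 0.15 FPKM. Whether these 4 genes changed independently, or as neighbours on a chromosome, was not tested. The authors' term of protein citrullination rests on the same 4 genes, so it is no separate evidence. A row shared by CEA, CEACAM5 and CEACAM6, which encode adhesion proteins of the carcinoembryonic antigen family, stood at 38.7 and 5.33 FPKM. A row shared by DDC8 and the protease inhibitor gene TIMP2 stood at 25.7 and 51.6 FPKM. H19, an imprinted long RNA, was listed at 0 in the control and 4315.5 in the knockout library with a status of no estimate, so its values are not a measurement of change.

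Cytosolic ribosomal protein genes were lower in the knockout library by a small and even amount, 63 of 65 measured, with a median log2 ratio of -0.27 and an interquartile range of -0.32 to -0.22. After removal of a trend on GC content, length and level the median was -0.25. Other genes matched on the longest transcript and level had a median of -0.037, and those matched on the length of protein-coding transcripts -0.0094. The matched genes were less abundant, with a median of 534 and 515 FPKM against 864 FPKM.

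Chromosome 7 loci were higher and chromosome 15 loci lower in the knockout library. A bias of GC content, transcript length or abundance is argued against, since removal of such a trend left medians of 0.39 and -0.25, against 0.35 and -0.27 before over the same genes. A difference in chromosome copy number between the cultures cannot be told apart from other causes by the share of windows on one side of 0. That share was 100% of the 16 windows of chromosome 7 and of the 9 windows of chromosome 15. It was also a median of 100% with the rows of chromosome 7 or 15 shuffled among its windows, so it could not decide. All windows of chromosomes 17, 19 and 22 also lay on one side, but nearer 0, at chromosome medians of -0.04 to -0.07. Windows ran from 0.16 to 0.47 on chromosome 7, from -0.54 to -0.20 on chromosome 15 and from -0.13 to -0.0039 on chromosome 17. On chromosome 1, the windows from 160 to 250 Mb had medians of 0.18 to 0.41. On chromosome 16, those from 0 to 40 Mb had 0.26 to 0.36 and those from 50 to 90 Mb -0.06 to -0.02. Such steps along a chromosome were not tested. DNA was not analysed here, the labels do not say whether the cells were clones or pools, and with 1 library per group an effect of the C1GALT1 knockout, untested here, also stays open.

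Integrin and laminin genes were higher and interferon-stimulated genes lower in the knockout library. The trend on GC content, length and abundance is argued against as the whole cause, since its removal left medians of 0.47 (SD 0.19 over resampled members) and -0.38 (SD 0.09). Subtraction of the median of the other loci in each member's 10 Mb window left 0.35 (SD 0.13) and -0.33 (SD 0.15), from 0.46 and -0.40. Those values lay farther than their spread from the bounds set beforehand for such a cause (0.15 and -0.15) but within their spread of the bounds set against it (0.25 and -0.25), so a part played by the shifted regions cannot be told apart from changes of these genes themselves. An effect of the C1GALT1 knockout and a difference between the cultures both stay open as untested.

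Several imprinted genes differed between the libraries, among them SNHG14 (49.8 and 1.13 FPKM), NDN (2.22 and 0.0061 FPKM), DIRAS3 (9.24 and 1.80 FPKM) and SGCE (8.91 and 19.4 FPKM). A candidate explanation is that imprinted genes differ between the 2 cultures more often than other genes, and 4 of 26 measured (15.4%) differed by 2-fold or more. Random lists matched on level had a median share of 3.8%, and the upper bound of their central 95% was also 15.4%. The percentile of the share, with tied lists counted in part, was 98.2, outside that range. The answer thus depends on how ties are counted, and with 26 genes the share cannot be told apart from chance. The list was drawn up after some of these genes had been seen to differ, and DNA methylation was not analysed here. SNHG14 and NDN lie on chromosome 15 and SGCE on chromosome 7, the chromosomes that shifted as a whole. SNHG14 and NDN also lie near each other, so they may not be independent.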
